A study of Homo sapiens with 12 samples.

How the data were processed

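Total RNA of 6 human pancreatic cancer cell lines was labelled with the dye Cy3 and hybridised to Agilent arrays that carry a single colour each. The lines form 3 pairs, the parental lines PK-1, PK-9 and PK-59 and the gemcitabine-resistant lines RPK-1, RPK-9 and RPK-59 derived from them, with 2 arrays per line and 12 arrays in all. Replicate numbers were taken from the sample titles. The labels do not say whether the arrays of a line came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

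The deposited scanner files give an intensity per spot, made with Agilent Feature Extraction, version 10.7.3.1 per the file headers and version 9.5.1 per the submitters' processing notes. The intensity used here is the processed signal, which is background-subtracted and spatially detrended within an array and not normalized between arrays, per the file headers and the values. The deposited value table held the same processed signal for every array, with a largest difference of 0 between its values and the scanner files, so it was not analysed as a separate set. Its column medians ran from 58.5 to 139, over its own set of spots. Each array held 45015 spots, of which 1639 were control spots, and 41000 different gene probes. Of these, 40736 were spotted once and 264 were spotted 10 times.

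Array annotation was on the NCBI36 (hg18) build, per the file headers. Probes were named through their RefSeq accessions with a gene table of the GRCh38.p14 assembly, which was used only for names and for the order of neighbouring genes. Because the builds differ, no coordinates are given. An accession match gave 1 symbol for 26222 probes and none for the other 14778, and the named probes stood for 17721 genes.

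The processed signal was put on the log2 scale and each array's 75th percentile over gene probes was subtracted. Spots that the scanner software marked as outliers were left out, which removed a value for 40 probes, and saturated spots were kept. Spots of a repeated probe were averaged. A probe was kept when the scanner software called it well above background on both arrays of at least 1 line, which left 28515 probes, 20588 of them with a symbol. Each gene was represented by the kept probe with the highest mean over the 12 arrays, and 5078 of the 13877 genes tested had more than 1 kept probe. Other probes are mentioned for DCK and for some of the genes where they disagree in direction, size or detection.

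Signal over background limits the precision of array values, as does the number of arrays. The 75th percentile of the signal ran from 729 to 1750 over the 12 arrays. The share of probes well above background was 59.0% to 68.1% in 11 arrays and 80.4% in replicate 1 of RPK-59. Across genes, the 2 arrays of a line correlated with r = 0.988 to 0.994 in 5 lines and r = 0.979 in RPK-59. Genes are not independent replicates, so these correlations only describe the arrays. The 2 arrays of each line held no identical values over the tested genes.

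The test was limma (lmFit and eBayes) on all 12 arrays with 6 group means, which share 1 estimate of the spread with 6 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Contrasts were the 3 differences of a resistant line from its parental line, their mean, and the 3 differences between those differences. No array is shared between the 3 line comparisons. Where a gene's probes were not well above background on either array of a line, the fold is given as a lower bound, written "at least". For the bound, the bright line's mean was set against the mean over the dim line's arrays of the higher of 2 values per array, the gene's own signal and the lowest signal among probes well above background. No fold is given where both lines were below background, and log2 differences of genes detected on only 1 array of a line are given with that number.

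Genes named in the text followed a rule written before the data were examined. The rule took DCK and the gemcitabine list, the 8 genes per direction and comparison with the largest change among those well above background and unsaturated on all 4 arrays and separated between the lines, up to 3 lower bounds per direction, genes called the same way in all 3 lines, the 6 largest differences among genes called in opposite directions in 2 lines, up to 4 called members of each list (with none called, the 2 with the smallest p), and members of the runs of neighbouring genes described. Unnamed open reading frames and clone names were left out of the ranked part. Some genes that the rule takes are not reported here.

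There were 21 gene lists with 525 places, written from textbook knowledge before the data were examined, of which 511 had a probe and 454 were tested. They covered gemcitabine uptake, activation and inactivation; pyrimidine synthesis and thymidylate; DCK neighbours at 4q13; drug efflux ABC transporters; p53 targets; DNA replication; mitotic proliferation; homologous recombination and Fanconi genes; epithelial and mesenchymal markers; interferon-stimulated genes; NF-kB cytokines and chemokines; hypoxia and glycolysis; NRF2 and glutathione genes; cholesterol synthesis; unfolded protein and amino acid stress; apoptosis regulators; pancreatic ductal and acinar markers; stem-like cell markers; and markers of fibroblasts and of blood and endothelial cells. Lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over 63 tests for the 3 comparisons and over the 21 lists for the mean.

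The arrays came from 3 slides, each scanned once, and the 4 arrays of a line pair shared a slide. Each comparison therefore lies within a slide, and slide as a block removes nothing from it, while differences between line pairs and slides cannot be separated by level. Replicate numbers paired arrays within a slide. Deviations from the line means correlated between same-numbered arrays with r = 0.366 for PK-1 and RPK-1, 0.317 for PK-9 and RPK-9 and 0.214 for PK-59 and RPK-59, across genes, and with r from -0.0017 to 0.234 between line pairs.

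Alternatives were quantile normalization, normexp background correction (offset 50) followed by quantile or 75th-percentile scaling, no filter or a filter on all 12 arrays, the replicate block within line pairs or shared by them, a variance trend, no fold minimum, limma's treat against 1.5-fold, other ways to combine probes, a fit on the 4 arrays of a comparison alone, the line pair as the unit, a common floor under all values, and leaving out each array. Normexp had been planned on the mean spot signal, a column not used here because the files analysed give the median spot signal, so the median spot and background signals were used. That substitution, the common floor and the count of runs without family neighbours were chosen after seeing the data.

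Neighbouring genes were compared with 1000 random orders of 13862 genes on the ordered chromosomes, and a run was at least 3 tested neighbours called in the same direction. The gene test was tested on simulated data with 200 changed genes among 13877. For RPK-1 it recovered 88% of 8-fold, 74% of 4-fold and 40% of 2-fold changes, with 4 false calls. For RPK-9 the shares were 88%, 74% and 36%, with 3 false calls, and for RPK-59 they were 86%, 82% and 20%, with 2 false calls. For the mean it recovered 96% of 8-fold and 40% of 2-fold changes, with 4 false calls. Changes of 1.5-fold, under the fold minimum, were recovered in 0% for RPK-1 and RPK-9 and 2% for RPK-59. Of changes made in all 3 lines, 88% of 8-fold, 78% of 4-fold and 2% of 2-fold were called in each line. A gene not called is thus not shown to be unchanged. The simulated noise of a gene had the same spread in every line, as the test assumes. In the data, the SD across genes of the difference between replicates was 0.748 in RPK-59, against 0.380 to 0.516 in the other lines. The simulated shares and false calls therefore cannot vouch for the calls in RPK-59. Nor can they vouch for its part in the mean, in the shared genes and in the differences between line pairs. Software was R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.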

Results

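Transcript levels were measured in 3 pairs of human pancreatic cancer cell lines on one-colour Agilent arrays that cover most known genes. Each pair joined a parental line, PK-1, PK-9 or PK-59, with a line derived from it, RPK-1, RPK-9 or RPK-59, that had acquired resistance to gemcitabine, a cytidine analogue used against pancreatic cancer. Each of the 6 lines was measured on 2 arrays, and the design text asks which molecules are key to the acquired resistance. The 75th percentile of the signal ran from 729 to 1750 over the 12 arrays. Replicate 1 of RPK-59 stood apart in its dim probes, with a 25th percentile of 39.3 against 4.25 to 7.75 in the other 11 arrays.

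The series title names DCK, deoxycytidine kinase, which adds the first phosphate to gemcitabine inside the cell. DCK fell to background in RPK-1 and RPK-9 and was well above background in RPK-59 and its parent. In PK-1 its normalized log2 signal was -0.36 ± 0.12 (SD, n = 2), and in RPK-1 it was not well above background on either array, which makes it at least 58.3-fold lower (limma adjusted p = 3.98e-07). In PK-9 the normalized log2 signal was -1.41 ± 0.16 (SD, n = 2), and the RPK-9 arrays were again not well above background, at least 18.2-fold lower (limma adjusted p = 2.97e-07). In RPK-59 the normalized log2 signal of DCK was -1.34 ± 0.02 against -0.91 ± 0.13 in PK-59 (SD, n = 2 each), a log2 difference of -0.43 that did not pass the test (limma adjusted p = 0.174). The other DCK probe gave the same picture, at least 16.9-fold lower in RPK-1 and at least 7.07-fold lower in RPK-9, with a log2 difference of -0.35 in RPK-59. With each probe both RPK-59 arrays lay below both PK-59 arrays, and a change under 2-fold could not be called at any p. Both probes match the transcript NM_000788. The difference between lines was itself tested, and the fitted log2 change of DCK in RPK-1 lay below that in RPK-59 by -7.05 (limma adjusted p = 6.70e-06) and that in RPK-9 by -5.85 (limma adjusted p = 7.71e-06). These differences include signals below background and give no fold.

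**Figure D1:**
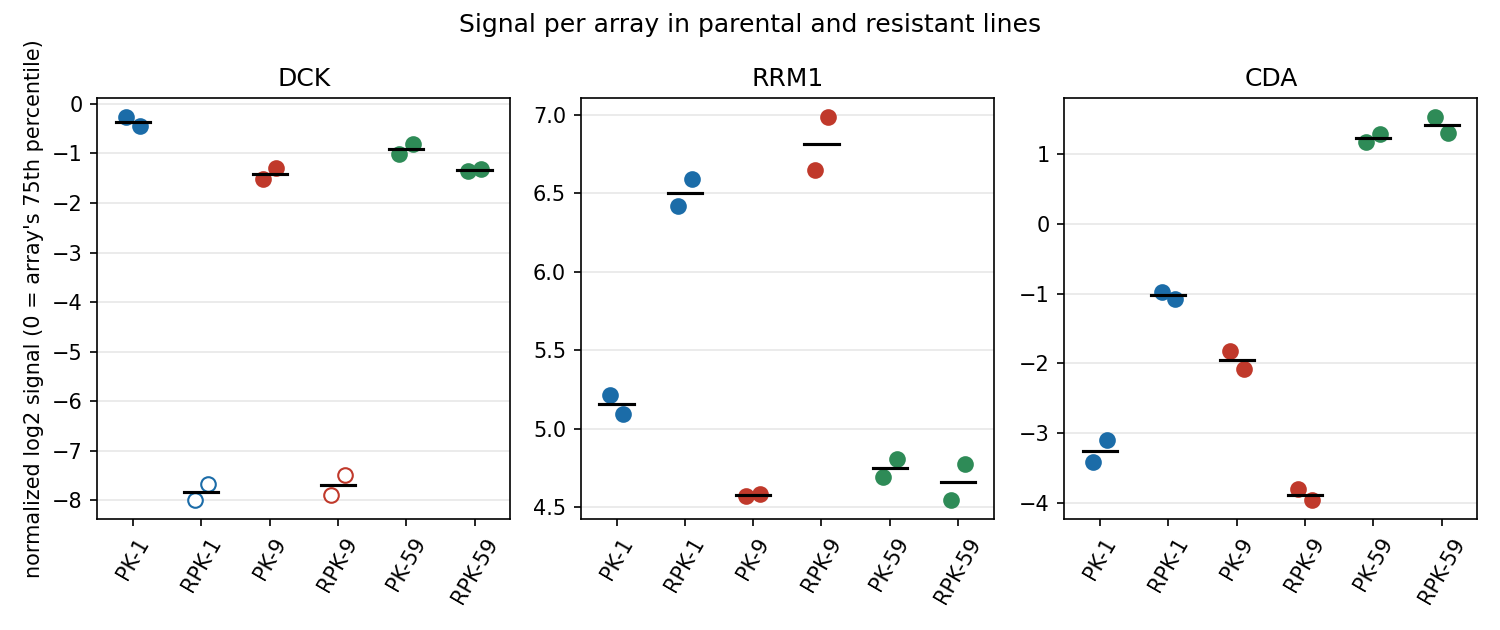
Normalized log2 signal, on which 0 is the array's 75th percentile, of DCK, RRM1 and CDA on each of the 12 arrays, with a bar at the mean of the 2 arrays per line, filled points for spots well above background and open points for spots that were not. DCK lies at background in RPK-1 and RPK-9 and at -1.34 in RPK-59, RRM1 is higher in RPK-1 and RPK-9 than in their parents, and CDA is higher in RPK-1 and lower in RPK-9. The vertical axes differ between the 3 genes.

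Of the other genes that take up, activate or inactivate gemcitabine, RRM1 rose in both lines that lost the DCK signal. RRM1 encodes the large subunit of ribonucleotide reductase, a target of gemcitabine diphosphate. It was higher by a log2 difference of 1.35 ± 0.16 in RPK-1 and 2.24 ± 0.16 in RPK-9 (SE, n = 2 each; limma adjusted p = 0.000925 and 3.64e-05), against -0.09 in RPK-59. In RPK-1, RRM1 was 1 of 6 neighbouring genes on chromosome 11 that were all called higher. CDA, the cytidine deaminase that inactivates gemcitabine, rose in RPK-1 by 2.23 on the log2 scale and fell by 1.93 in RPK-9 (limma adjusted p = 8.56e-05 and 9.81e-05), and these changes differed by 4.16 (limma adjusted p = 1.49e-05). The nucleotidase gene NT5M rose in RPK-1, with a log2 difference of 1.97 (limma adjusted p = 0.0269). In RPK-9 the nucleoside transporter gene SLC29A2 rose by 2.00 and the nucleotidase gene NT5C fell by 1.60 on the log2 scale (limma adjusted p = 0.000452 and 0.000597).

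Counted over the 19 tested members of this list, 3 were called higher and 1 lower in RPK-1, 2 higher and 3 lower in RPK-9, and 0 in RPK-59. Adjusted over the list alone, the counts were 4, 5 and 0. Camera did not call the list in any line, whereas fry, which does not set a list against other genes, called it lower in RPK-9 (adjusted p = 0.00243). DCK, whose fitted change includes signals below background, is a member, and the list's median log2 difference in RPK-9 was -0.39. The list was not tested without DCK. In RPK-59 the members with the smallest p were SLC29A2, with a log2 difference of -0.68 (limma adjusted p = 0.0914), and DCK. The changes of RRM1 in RPK-1 and RPK-9 each differed from that in RPK-59, by 1.44 and 2.33 on the log2 scale (limma adjusted p = 0.00483 and 0.000317). Under normexp with the 75th percentile, CDA was no longer called in RPK-1, at 0.87, or RPK-9, at -1.16, nor NT5M in RPK-1, at 0.68. NT5M also lost its call without RPK-1 replicate 1, at 1.59, or PK-1 replicate 2, at 1.53, and quantile normalization called SLC29A2 lower in RPK-59, at -1.03.

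**Figure D2:**
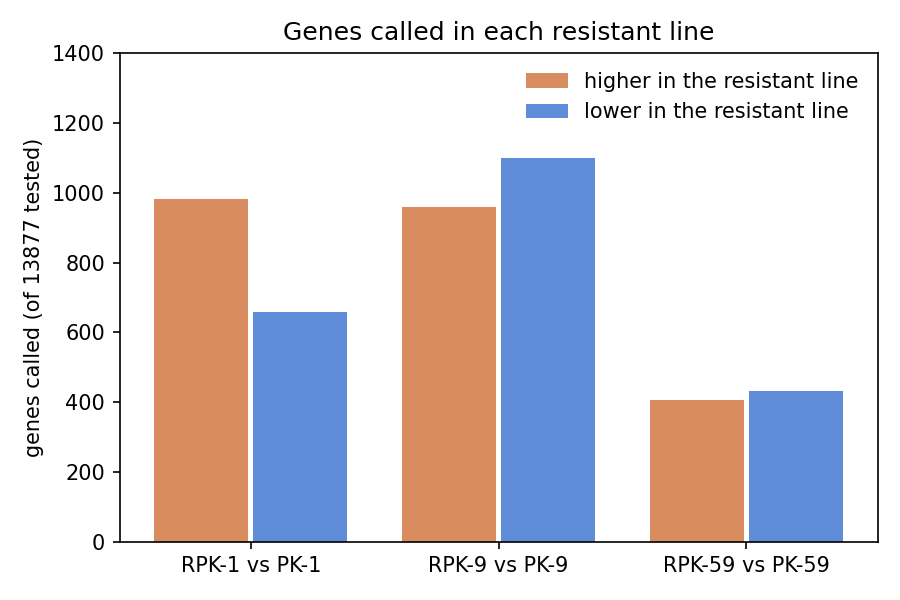
Number of genes called higher (orange) or lower (blue) in each resistant line against its parental line, of 13877 genes tested with limma at an adjusted p under 0.05 and a change of at least 2-fold. RPK-9 has the most calls, 958 higher and 1098 lower, and RPK-59 the fewest, 406 higher and 432 lower.

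RPK-1 differed from PK-1 in 1640 of 13877 genes, 983 called higher and 657 lower. Among genes measured on all 4 arrays, the largest falls were in DUSP23, a dual-specificity phosphatase gene, 173-fold lower (log2 -7.43 ± 0.25, SE), in CAVIN3, a component of caveolae, at -6.78, and in the basement membrane collagen gene COL4A2 at -5.53. SPOCK2 followed at -4.65, the troponin gene TNNI2 at -4.04, the intermediate filament gene VIM at -4.02, the chaperone gene DNAJA4 at -3.99 and CGAS, the sensor of cytosolic DNA, at -3.80. The largest rises were in the peptide transporter gene SLC15A3, 53.9-fold higher (log2 5.75 ± 1.10, SE), in the collagen gene COL6A1 at 5.39, in NRXN2 at 5.00, in LYPD1 at 4.52 and in the potassium channel gene KCNH2 at 4.44. GGTLC1, GGTLC2 and GGT3P also rose, at 4.28, 4.18 and 4.17, but belong to a family of near-identical genes whose probes can share signal. Genes below background in PK-1 included NALF2, at least 124-fold higher, the activin subunit gene INHBB, at least 78.2-fold higher, and WNT3A, at least 68.8-fold higher. Below background in RPK-1 were TUSC1, at least 98.1-fold lower, and the serine synthesis gene PSAT1, at least 71.4-fold lower. The adjusted p of these genes ran from 7.35e-07 for NALF2 to 0.00735 for SLC15A3 (limma).

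Some of these values depended on the probe, the scaling or a single array. A second probe put CAVIN3 at -1.96, and second probes of COL6A1 and LYPD1 were not well above background in either line. Normexp with the 75th percentile gave 264 genes higher and 328 lower, and NRXN2, GGT3P and WNT3A were then not called. Without RPK-1 replicate 1 the higher calls fell in number more than the lower calls.

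By gene list, 8 of 28 interferon-stimulated genes rose in RPK-1 and 2 fell, a shift upwards with camera at a preset correlation (adjusted p = 0.0379). Adjusted p was 0.978 with an estimated correlation, and 0.0816 with the replicate number as a block. Called members included XAF1, at 4.19 on the log2 scale and detected on 1 of 2 PK-1 arrays, the antiviral synthetase gene OAS2, at least 3.71-fold higher, IFI44L at 3.11 and OASL at -2.25. The DCK neighbours at 4q13 shifted downwards (camera adjusted p = 0.00065 with the preset correlation), with 4 of 15 tested members lower and 0 higher. Adjusted p was again 0.978 with an estimated correlation. The called members were the chemokine gene CXCL1, at least 1.92-fold lower, RUFY3 at -1.66, the growth factor gene AREG at -1.48 and the chemokine gene CXCL2 at -1.24. The call of CXCL1 rests on a fitted change that includes signals not well above background, and its bound is under 2-fold. The call of the interferon list was also lost without PK-1 replicate 1 (adjusted p = 0.221), RPK-1 replicate 1 (0.0754), RPK-9 replicate 1 (0.0524) or either RPK-59 array (0.0551).

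Camera and fry called no other list in RPK-1. Of the mesenchymal markers 2 of 22 rose and 3 fell, with VIM at -4.02, WNT5A at least 3.21-fold higher and CCN2 at -2.65 with 1 RPK-1 array above background, while 0 of 24 epithelial markers were called and the smallest p were those of ELF3 at 1.00 and RAB25 at -0.48. Cholesterol synthesis genes gave 4 higher and 2 lower of 25, with the lanosterol synthase gene LSS at 1.41, TM7SF2 at 1.34 and MSMO1 at 1.14 among the higher. ABC transporters gave 3 higher and 1 lower of 17, with ABCA3 at least 6.71-fold higher and ABCC6 at 3.08. Among apoptosis regulators, 1 of 27 rose and 2 fell, the pro-apoptotic genes BIK at -3.54 and BMF at 2.25 and the anti-apoptotic gene BCL2 at -1.72. Hypoxia and glycolysis genes gave 3 higher of 27, with the glucose transporter gene SLC2A3 at 2.81, detected on 1 PK-1 array, and ENO2 at 1.46. NF-kB cytokines and chemokines gave 1 higher and 3 lower of 21, with CXCL1 and PTGS2 at -1.59. The p53 targets GADD45A at -1.54 and PLK2 at -1.42 were the 2 of 24 called, and the pyrimidine genes DPYD at -1.75, with other probes at -1.36 and 0.81, and UCK2 at -1.05 were the 2 of 19 called.

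Of 31 DNA replication genes 0 were called in RPK-1, with MCM2 at 0.52 and ORC1 at -0.66 having the smallest p. Among 27 mitotic genes CDC20 fell, at -1.17, and FOXM1 rose, at 1.09. Homologous recombination and Fanconi genes gave 2 higher and 1 lower of 27, with FANCA at -1.32 and FANCG at 1.04. The NRF2 list gave 1 of 24, SRXN1, at -8.84 with 1 RPK-1 array above background. In the unfolded protein and amino acid list, PSAT1 fell and HERPUD1 rose, at 1.39, of 25. Pancreatic markers SOX9 at -1.38 and AGR2 at 1.17 were called of 15, and stem-like markers gave 1 higher and 2 lower of 16, with CXCR4 at 3.35 and JAG1 at -1.31. Fibroblast markers gave 2 higher and 1 lower of 11, with FSTL1 at 1.19, FBN1 at -1.12 and ACTA2 detected on 1 PK-1 array, and blood and endothelial markers gave VWF at 3.97, detected on 1 PK-1 array, and CD68 at -1.08 of 10.

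RPK-9 differed from PK-9 in 2056 genes, 958 called higher and 1098 lower. Among genes measured on all 4 arrays the largest rises were in VILL, a villin-like gene, 102-fold higher (log2 6.68 ± 0.31, SE), in the calcium-binding protein gene CALB1 at 6.19, and in PSAT1 at 6.16, which had fallen in RPK-1. The aldo-keto reductase gene AKR1C1 rose by 5.97, the ceruloplasmin gene CP by 5.81, DGLUCY by 5.39 and the calcium-binding protein gene S100P by 5.39 on the log2 scale. The largest falls were in FKBP10, a prolyl isomerase gene, 187-fold lower (log2 -7.55 ± 0.17, SE), in the transglutaminase gene TGM2 at -6.51, TM4SF1 at -6.44, OASL at -6.42, the carboxypeptidase gene CPE at -6.21, the actin-binding protein gene CALD1 at -5.96, HEG1 at -5.53 and ADAP2 at -5.51. Below background in PK-9 were ZNF22, at least 289-fold higher, RAB38, at least 166-fold higher, and the alcohol dehydrogenase gene ADH1C, at least 139-fold higher. FUOM, IAH1 and the inflammasome adaptor gene PYCARD were below background in RPK-9, at least 371-fold, 342-fold and 255-fold lower. The adjusted p of these genes ran from 1.14e-08 for ZNF22 to 0.00825 for S100P (limma), and the call of S100P was lost without PK-9 replicate 1, at 4.69, or RPK-9 replicate 1, at 4.54.

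The interferon-stimulated genes moved the other way in RPK-9, with 13 of 28 lower and 3 higher (camera adjusted p = 0.00333 with the preset correlation, and adjusted p = 0.978 with an estimated correlation). Besides OASL, they included HERC5, at least 6.13-fold lower, IFI44 at -4.53 and IFIT1 at -3.99. The NRF2 and glutathione genes shifted upwards, with 6 of 24 higher and 0 lower (camera adjusted p = 0.00674 with the preset correlation, and adjusted p = 0.978 with an estimated correlation). Besides AKR1C1, they included AKR1C3 at 5.26, AKR1B10 at 4.81 and the glutathione peroxidase gene GPX2 at 2.61. The NRF2 call was lost without RPK-9 replicate 1 (adjusted p = 0.0524).

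**Figure D3:**
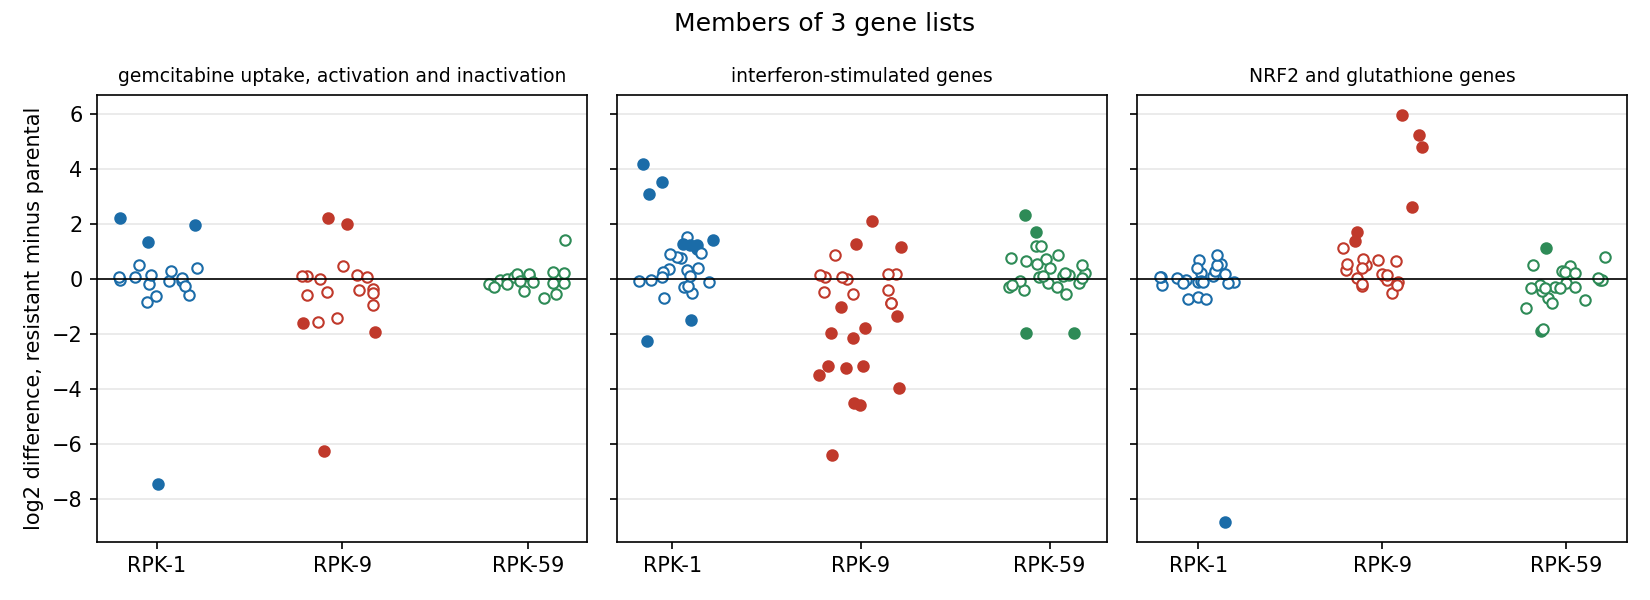
Log2 difference of each tested member of 3 gene lists in the 3 resistant lines, resistant minus parental, with filled points for called genes and open points for the others. The panels show the gemcitabine list with 19 genes, the interferon-stimulated genes with 28, of which 13 are called lower in RPK-9, and the NRF2 and glutathione genes with 24, of which 6 are called higher in RPK-9.

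Camera called no other list in RPK-9, while fry also called the epithelial markers lower (adjusted p = 0.00432). Of the epithelial markers 3 of 24 fell, the keratin gene KRT7 at -1.68, the tight junction gene TJP1 at -1.41 and CLDN7 at -1.27. Mesenchymal markers gave 5 lower and 1 higher of 22, with VIM at least 23.4-fold lower, fibronectin (FN1) at least 6.42-fold lower, the receptor gene AXL at -2.26 and the lysyl oxidase gene LOX at least 8.95-fold higher. NF-kB cytokines and chemokines gave 4 higher and 5 lower of 21, with CXCL1 at 3.39, CXCL8 at 2.84 and CCL5 at least 5.14-fold lower. The DCK neighbours gave 3 higher and 1 lower of 15, with MOB1B at least 34.2-fold lower and the bicarbonate transporter gene SLC4A4 at least 16.6-fold higher. Pancreatic markers gave 4 higher and 1 lower of 15, with SPP1 at -5.18 and the trefoil factor gene TFF3 at 3.68. TFF1 was called by a probe not detected on either PK-9 array, and its other probe, detected on all 4 arrays, was at 0.33. Stem-like markers gave 3 higher and 2 lower of 16, with NES at -5.52, detected on 1 RPK-9 array, and ALDH1A1 at least 6.15-fold higher. Unfolded protein and amino acid stress genes gave 4 higher of 25, PSAT1, VLDLR at 3.29, DNAJC3 at 1.75 and XBP1 at 1.51.

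Of the remaining lists in RPK-9, ABC transporters gave 3 higher and 1 lower of 17, with ABCG1 at 2.56 and ABCA1 at 2.09, and hypoxia and glycolysis genes gave 2 and 2 of 27, with SLC2A3 at least 52.7-fold lower and ENO2 at 2.42. Apoptosis regulators gave 1 higher and 2 lower of 27, with BMF at -1.82, BCL2 at 1.77 and CFLAR at -1.36, whose other probe was at -0.27, so that BMF and BCL2 were called in the directions opposite to those in RPK-1. DPYD was the 1 called of 19 pyrimidine genes, at 1.76, and was called the other way in RPK-1. A second probe ran the same way, at 1.49 in RPK-9 and -1.36 in RPK-1, whereas the remaining probe ran the opposite way in both lines, at -1.09 in RPK-9, where it was not detected on either array, and 0.81 in RPK-1. Among p53 targets 2 of 24 were called, TP53I3 at -1.26 and ZMAT3 at 1.31, the latter detected on 1 RPK-9 array. EXO1 fell, at -1.63, and CHEK2 rose, at 1.18, among 27 homologous recombination genes, and cholesterol genes gave 1 higher and 1 lower of 25, with PMVK at -1.07. Of 31 DNA replication and 27 mitotic genes 0 were called, with CHEK1 at -0.86, UHRF1 at -0.80, CENPE at -0.85 and CCNA2 at -0.90. Fibroblast markers gave 1 higher and 2 lower of 11, with FSTL1 at -3.84 and MFAP5 at least 2.59-fold lower, and of 10 blood and endothelial markers CD68 fell, at -1.35.

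RPK-59 differed from PK-59 in 838 genes, 406 called higher and 432 lower. Among genes measured on all 4 arrays the largest falls were in CYP26A1, which clears retinoic acid, 82.0-fold lower (log2 -6.36 ± 0.24, SE), in the keratin gene KRT4 at -6.17, in the WNT inhibitor gene APCDD1 at -5.52, in the kallikrein genes KLK11 and KLK7 at -4.84 and -4.03, in RAB34 at -4.56, in RHOU at -4.38 and in the protease inhibitor gene SPINK5 at -4.09. Rises were largest in the galanin-like peptide gene GALP, 42.6-fold higher (log2 5.41 ± 0.83, SE), in the inflammasome gene NLRP3 at 5.28, in the kallikrein gene KLK5 at 4.39, in the potassium channel gene KCNS3 at 4.04, in TRIM6 at 3.87, PARM1 at 3.71, TMEM71 at 3.55 and EMB at 3.37. Carbonic anhydrase-like CA8, the lysyl hydroxylase gene PLOD2 and PARP8 were below background in PK-59 and at least 23.4-fold, 21.4-fold and 14.6-fold higher in RPK-59. The neuropeptide gene GAL, BEX3 and the cortisol-activating enzyme gene HSD11B1 were below background in RPK-59, at least 369-fold, 47.1-fold and 42.1-fold lower. The adjusted p of these genes ran from 1.35e-05 for CYP26A1 and GAL to 0.00784 for KLK5 (limma).

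With the spread taken from its own 4 arrays alone, 15 genes were called in RPK-59, 6 higher and 9 lower, against 1785 in RPK-1 and 2186 in RPK-9. Quantile normalization gave 352 higher and 765 lower, normexp with quantile 187 and 350, and without RPK-59 replicate 1, the array with raised dim signals, there were 294 higher and 518 lower, whereas without replicate 2 there were 1032 and 335. Of the genes named, GALP, NLRP3, KLK5, PARM1, TMEM71, CA8, PLOD2, APCDD1, KLK11, RHOU, KLK7 and HSD11B1 were not called under normexp with the 75th percentile, which called 136 genes.

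In RPK-59 no gene list passed the test as a whole. Interferon-stimulated genes gave 2 higher and 2 lower of 28, with HERC5 at 2.32, OAS1 at -1.97 and IFIT2 at 1.71, and NRF2 genes gave 1 and 1 of 24, with AKR1C1 at -1.89, whose other 2 probes were at -2.15 and -0.56. AKR1B10 was called by a probe not detected on either PK-59 array, and its other probe, detected on both, was at 0.07. Mesenchymal markers gave 2 and 2 of 22, with WNT5A at least 3.39-fold higher, ITGA5 at -1.18 and MMP14 at -1.16, and the epithelial regulator gene GRHL2 rose, at 1.26, as the 1 called of 24 epithelial markers. Pancreatic markers gave 1 higher and 3 lower of 15, with SPP1 at -9.16, detected on 1 RPK-59 array, TFF2 at -1.79 and FOXA2 at -1.19, whose other 2 probes were at -1.68 and 0.57, both detected on fewer RPK-59 arrays. The p53 targets FAS at 1.61 and GADD45A at 1.27 rose of 24, and among 27 apoptosis regulators BIRC3 rose, at 1.33, and BCL2 fell, at -1.06. BIRC3 was also the 1 called of 21 NF-kB genes, NDRG1 at -1.28, with its other probe at 0.12, the 1 of 27 hypoxia genes, and HMMR at 1.09 the 1 of 27 mitotic genes. Stem-like markers JAG1 at -1.12 and HEY1 at -1.07 fell of 16. Fibroblast markers gave 1 higher and 3 lower of 11, with DCN at least 3.71-fold lower and COL5A1 at -2.65, detected on 1 RPK-59 array, and of 10 blood and endothelial markers CD68 fell, at -1.17.

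There were 0 called members in RPK-59 among 15 DCK neighbours, 17 ABC transporters, 19 pyrimidine, 31 DNA replication, 27 homologous recombination, 25 cholesterol and 25 unfolded protein and amino acid stress genes. Their smallest p belonged to SLC4A4, detected only in PK-59 and at least 1.78-fold lower by its signal bound, and CXCL1 at -1.21, ABCC4 at 0.91 and ABCB10 at -0.68, MTHFD1 at -0.47 and TYMP at -0.61, POLE2 at -0.71 and CDC45 at 0.59, FANCC at 0.48 and FANCL at 0.57, CYP51A1 at -0.68 and SQLE at -0.58, and PHGDH at -2.28 and HSPA5 at -0.63.

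Over the 63 tests of lists in the 3 comparisons, camera called 4 with the preset correlation, and 0 with an estimated correlation. With the estimated correlation 2 had an unadjusted p under 0.05, no more than chance alone would give. Fry, which asks whether a list's genes move on balance one way and does not set them against other genes, called 6, those 4 and the gemcitabine list and epithelial markers in RPK-9. Without RPK-9 replicate 1 the preset correlation called 2 lists, and without PK-1 replicate 2 or RPK-9 replicate 2 it called 7. The 4 called lists kept their calls under each scaling tried with the preset correlation, and their medians, means and tests had the same sign. Counts of members adjusted over the list alone equalled those of genes with an adjusted p over all genes and at least 2-fold in most lists, and differed most for NF-kB genes in RPK-9, 11 against 9, and for mesenchymal markers, 6 against 4, and blood and endothelial markers, 6 against 1, in RPK-59.

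To ask what the 3 resistant lines had in common, genes called in the same direction in each were counted. There were 31, 17 higher and 14 lower, where independent lists would give 1.99 and 1.62. The lists share 1 estimate of the spread per gene and so are not independent, and the excess alone shows no shared response. In simulated data 2% of 2-fold changes made in all 3 lines were called in each, so the count misses small shared changes. Measured on all arrays and higher in each line were AGR2, a protein disulfide isomerase gene of secretory epithelia, with log2 differences of 1.17, 1.71 and 1.11 in RPK-1, RPK-9 and RPK-59, ICA1 with 1.53, 2.84 and 1.56, the fatty acid oxidation gene CPT1B with 1.29, 1.30 and 1.14, COL11A2, MARCHF3 and PXYLP1. Lower in each were BMP4, a bone morphogenetic protein gene, with -1.88, -2.34 and -1.10, the phosphatase gene DUSP5 with -1.93, -1.13 and -1.01, TERT, the catalytic subunit of telomerase, with -1.68, -1.51 and -3.42, and BAG2, CD68, KLHDC9 and SDR16C5. Shared genes not detected on at least 1 array were ADAM28, CDH7, KLRG1, LKAAEAR1, MSMB, PPP1R1C, PRKAR2B, RCAN2, SUSD4, TLE4 and TLR5 among the higher, and EPGN, GSTM3, HEY1, NOSTRIN, OR2A7, PTX3 and ZNF239 among the lower. CDH7 lost its call in RPK-1 with the replicate number as a block within line pairs. Quantile normalization gave 9 higher and 18 lower, normexp with quantile 4 and 5, and normexp with the 75th percentile 0 genes, turning the sign in RPK-1 for CDH7, COL11A2, KLRG1, LKAAEAR1, PPP1R1C, PRKAR2B, RCAN2 and TLR5 and in RPK-59 for BAG2, HEY1 and OR2A7. Without RPK-1 replicate 1 the shared higher genes fell in number more than the shared lower genes. With the spread taken from its own 4 arrays alone, RPK-59 had 6 genes called higher and 9 lower. No more than these could be shared without the pooled spread. Leaving out 1 array gave 18 genes without PK-1 replicate 1, 15 without its replicate 2, 16 without RPK-1 replicate 1, 20 without either PK-9 array, 16 and 18 without replicates 1 and 2 of PK-59, and 56 without RPK-59 replicate 2. Of the genes measured on all arrays, ICA1 kept its call in each line whichever array of that line pair was left out, and each of the others lost at least 1 call, TERT in RPK-1 and RPK-9 without any 1 of their arrays.

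Between RPK-1 and RPK-9, 318 genes were called in opposite directions, where independent lists would give 123, and 130 were higher in both and 106 lower in both, where independent lists would give 67.9 and 52.0. Opposite calls included the insulin-like growth factor binding protein gene IGFBP3, lower in RPK-1 and higher in RPK-9, with fitted changes that differed by -13.83 on the log2 scale. PSAT1 differed by -13.18, ZNF22 by -12.60, WNT3A, higher in RPK-1 and lower in RPK-9, by 12.24, and the keratin gene KRT6B by -11.59. These differences include signals below background and give no fold, and a second IGFBP3 probe, above background on all 8 arrays, gave -4.54 in RPK-1 and 4.26 in RPK-9. RPK-1 and RPK-59 shared 83 genes higher and 48 lower, with 93 opposite, where independent lists would give 28.8, 20.5 and 49.8. RPK-9 and RPK-59 shared 75 and 91, with 117 opposite, where independent lists would give 28.0, 34.2 and 61.9. Same-direction and opposite calls thus both exceeded these values in each pair of lines. Across genes, log2 changes correlated with Pearson r = -0.033 for RPK-1 and RPK-9, 0.122 for RPK-1 and RPK-59 and 0.017 for RPK-9 and RPK-59, where genes are not independent replicates.

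These overlaps moved with the processing. Normexp with the 75th percentile gave 63 genes in the same direction and 72 opposite for RPK-1 and RPK-9, 13 and 8 for RPK-1 and RPK-59, and 23 and 17 for RPK-9 and RPK-59, against 236 and 318, 131 and 93, and 166 and 117. Quantile normalization gave 187 opposite calls for RPK-9 and RPK-59. For RPK-1 and RPK-59, the genes in the same direction numbered 304 without RPK-59 replicate 2, 85 without PK-1 replicate 1 and 77 without RPK-1 replicate 1, and the opposite calls 60 without RPK-1 replicate 1, 61 without PK-1 replicate 2 and 48 without PK-59 replicate 1. For RPK-9 and RPK-59, 95 genes were called in the same direction without PK-59 replicate 1 and 259 without RPK-59 replicate 2, which gave 203 opposite calls.

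For the mean of the 3 changes, 882 genes were called, 555 higher and 327 lower. Of the gemcitabine list 1 member was higher, RRM1, at a mean log2 change of 1.17, and 1 was lower, DCK, and 0 lists were called with either correlation, with 2 under an unadjusted p of 0.05 at the preset one. Fry called the gemcitabine list and the DCK neighbours lower (adjusted p = 0.00486 and 0.0113). DCK, whose fitted change includes signals below background, is a member of the gemcitabine list. That list had a median of -0.11 against a mean of -0.25, and it was not tested without DCK. The test of the mean uses the spread between arrays and speaks only of these 3 lines. With the line pair as the unit limma called 0 genes. An unadjusted p under 0.05 was reached by 643 of 13877 genes, no more than chance alone would give. For the mean, quantile normalization gave 394 higher and 453 lower, normexp with quantile 105 and 123, and normexp with the 75th percentile 87 and 105. Turning the direction of the PK-9 pair gave 953 calls, more than the 882 of the real direction.

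The genes next to DCK on chromosome 4 were set in the order of the GRCh38.p14 annotation. In RPK-9 the adjoining gene MOB1B fell with DCK, at least 34.2-fold, while the tested gene on the other side, SLC4A4, rose, at least 16.6-fold. In RPK-1 MOB1B was at -0.98 and was not called, being under 2-fold, and RUFY3 was the nearest called gene, at -1.66 by a probe whose partner, detected on all 4 arrays, was at -0.68, with UTP3 at -0.86, GRSF1 at -0.80, COX18 at -0.53 and ANKRD17 at -0.98 (limma adjusted p from 0.00622 for MOB1B to 0.0463 for COX18). In RPK-59 MOB1B was at 0.10 and GRSF1 at -0.24.

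**Figure D4:**
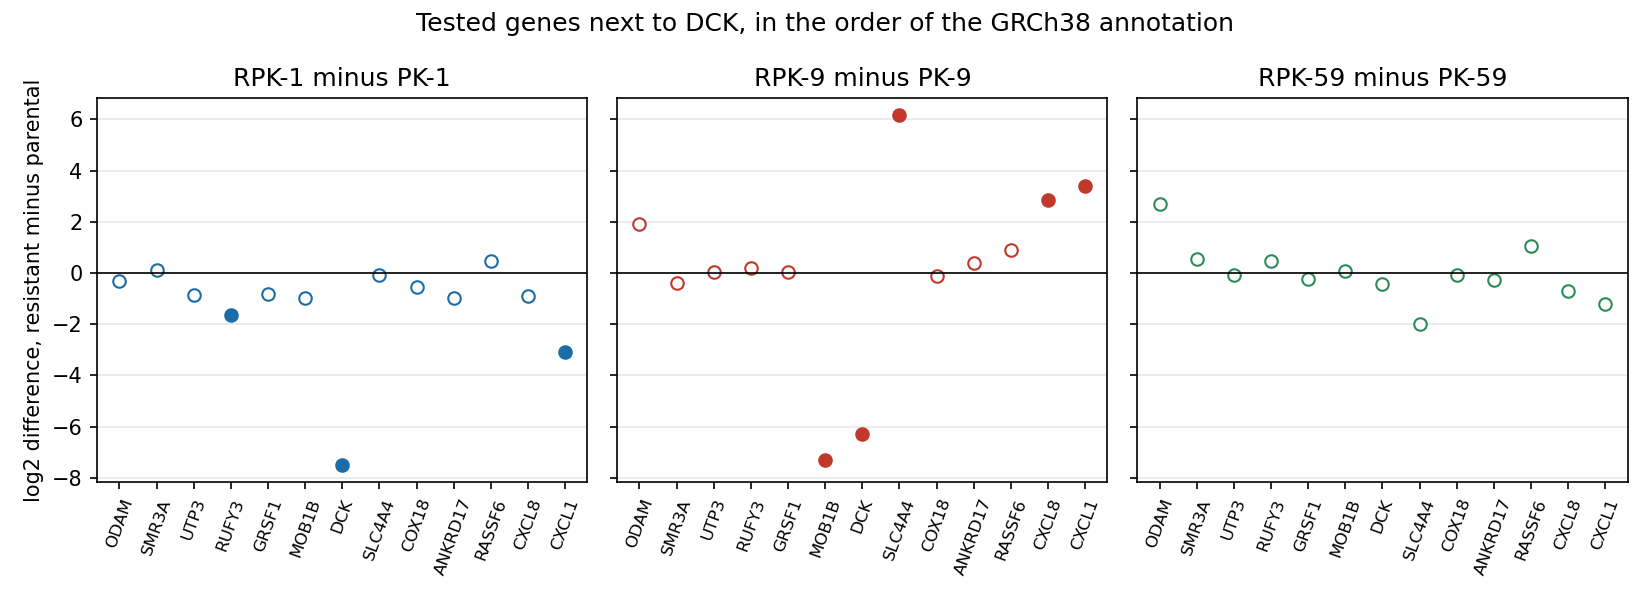
Log2 difference, resistant minus parental, of DCK and the 6 tested genes on either side of it in the 3 lines, in the gene order of the GRCh38 annotation, with filled points for called genes. DCK is called lower in RPK-1 and RPK-9, at least 58.3-fold and 18.2-fold, and MOB1B in RPK-9, at least 34.2-fold, their plotted differences including signals not well above background, and DCK is at -0.43 in RPK-59.

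Genes called in the same direction lay next to each other more often than in shuffled orders. In RPK-1 there were 27 runs of at least 3 neighbours called lower and 21 called higher, where 1000 shuffled orders gave means of 1.33 and 4.55. RPK-9 had 34 runs lower and 29 higher, where shuffled orders gave 6.32 and 4.23, and RPK-59 had 0 lower and 5 higher, where they gave 0.378 and 0.331. The permutation p was 0.000999 for each except the lower runs of RPK-59, the smallest that 1000 permutations can give. A stretch of chromosome 13, taken from the first to the last run there that was higher in RPK-9, held 90 consecutive tested genes, of which 56 were called higher and 3 lower, among the higher the DNA repair gene ERCC5 at 1.92, the ubiquitin ligase gene CUL4A at 1.82, the E2F partner gene TFDP1 at 1.75 and the lysosomal gene LAMP1 at 1.36. The median log2 difference of the 90 genes was 1.38 in RPK-9, -0.02 in RPK-1 and 0.13 in RPK-59.

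**Figure D5:**
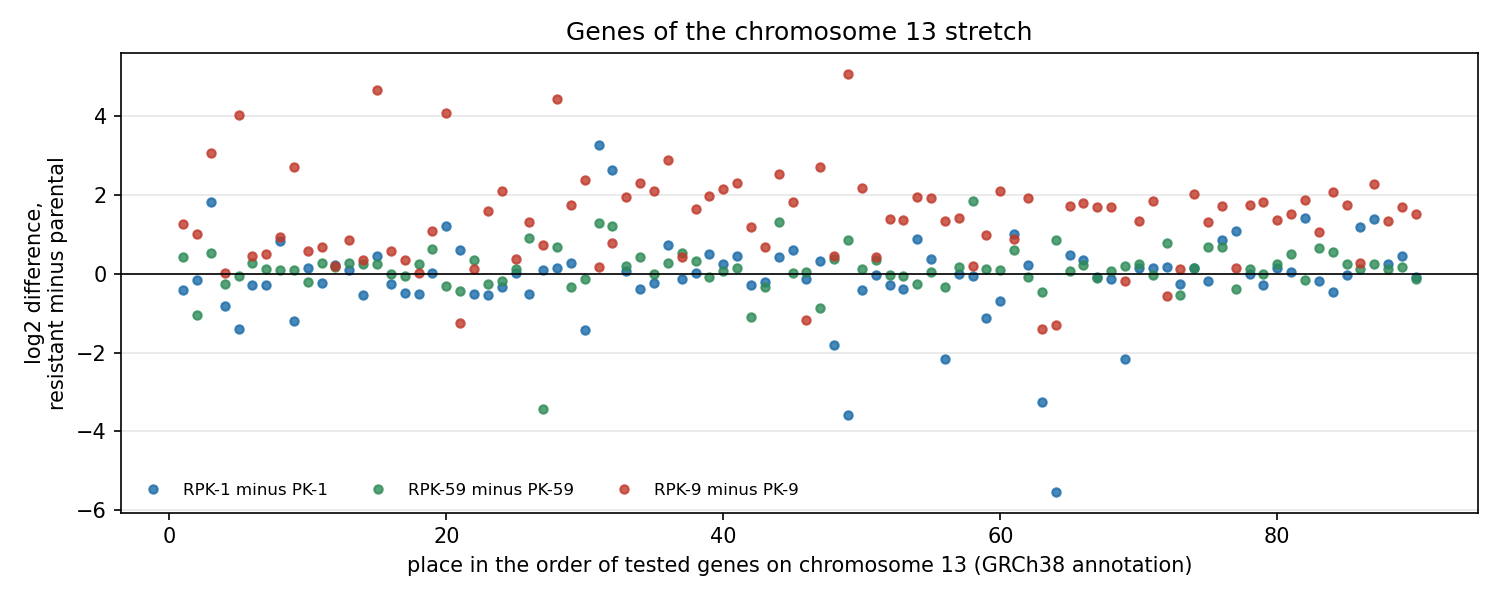
Log2 difference, resistant minus parental, of the 90 tested genes of a stretch of chromosome 13, by their place in the gene order of the GRCh38 annotation, in the 3 line pairs. RPK-9 has a median of 1.38 with 93.3% of its genes above 0, and the medians of RPK-1 and RPK-59 are -0.02 and 0.13.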

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

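The tests of chance neighbours, of the loss of DCK and MOB1B and of the scanner background were chosen after the result was seen, and the bound for the starting levels was tightened then. The count without family neighbours was added after seeing the data, with its bound written before its result. Groups of 2 arrays were not tested for outliers.

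The change on resistance differed between the line pairs, by a limma test of the difference itself, in 2965 genes for RPK-1 against RPK-9, 1715 for RPK-1 against RPK-59 and 2518 for RPK-9 against RPK-59. The counts that involve RPK-59 rest on the pooled spread, although its replicates differed more than those of the other lines. Without RPK-1 replicate 1 the difference between RPK-1 and RPK-59 was called for 1131 genes. Among genes called in opposite directions, the change in RPK-1 minus that in RPK-9 was -13.83 on the log2 scale for IGFBP3, -13.18 for PSAT1, -12.60 for ZNF22, 12.24 for WNT3A and -11.59 for KRT6B. DCK differed by -7.05 between RPK-1 and RPK-59 and by -5.85 between RPK-9 and RPK-59. Most of these differences include signals below background and give no fold. Probes without a gene symbol, which enter no comparison of genes, held calls as well, 664 of 7915 in RPK-1, 840 in RPK-9 and 371 in RPK-59, of which 282 were higher and 89 lower.

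Neighbouring genes were called in the same direction in 116 runs over the 3 lines, and 77 runs were left when 866 genes sharing their first 3 letters with the gene before were left out. Shuffled orders argue against chance neighbours, with at most 32 runs in 1000 orders, and against families of like symbols as the whole cause, with at most 26. The rule goes by symbol alone, so neighbours that share sequence under other symbols would have stayed in. Most genes of the chromosome 13 stretch rose in RPK-9, with 84 of 90 above 0, in a stretch chosen to begin and end with higher runs. Whether the rise takes in the whole block, as a gain of DNA could give, stays open. The 31 uncalled genes had a median of 0.428, between the median of -0.0003 and the highest value of 0.588 for uncalled genes of 1000 stretches elsewhere, and leaving out called genes removes the largest changes. The loss of 1 DNA segment holding DCK and MOB1B in RPK-9 also stays open, as each of the 3 probes was well above background in PK-9 and not in RPK-9, and no DNA was measured. The same held for 0.598% of the 18380 probes as bright. The loss of both signals was known before this test, so that share gives it no separate weight. Shared regulation of neighbouring genes was not tested.

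Replicate 1 of RPK-59 had raised dim signals. A higher scanner or hybridisation background as the whole cause is argued against by the negative control spots, which rose by 0.750 on the log2 scale over the other 11 arrays, against 2.90 for the 25th percentile of gene probes. These are background-subtracted signals, which can hide a raised background. The raw median of the negative controls was 93, against 79 to 86 on the rest of its slide and 72 to 95 over the other 11 arrays. The raw local background was 58.5, against 52 to 69. RNA of a line from another pair is argued against by 230 probes bright in both other line pairs. Their median rise over replicate 2 was 1.66, which differed by -0.157 from that of 9955 probes dim in all other arrays. The 230 probes were chosen to be dim in PK-59, so they cannot speak on RNA of PK-59. Labelling or RNA quality was not tested, since the labels give neither. With only 2 arrays of RPK-59, which of them is closer to the line cannot be settled, and no biological explanation was tested because both carry the same label.

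RPK-1 and RPK-9 held 318 opposite calls, of which 211 were higher in RPK-1 and lower in RPK-9. A full mix-up of the lines is argued against, as 36.7% of 150 genes silent in PK-1 and high in PK-9 were called higher in RPK-1, and 25.9% of 158 such genes the other way round in RPK-9, both under the 75% set before the test. That bound was chosen and not derived, so a partial mixture of RNA is not excluded. Over all 13877 genes the shares called higher were smaller, 983 genes in RPK-1 and 958 in RPK-9. Different starting levels in the parental lines stay open, since 75.5% of the opposite calls were higher in the parental line whose resistant line fell, over the 75% set before the test but with an exact binomial interval, required afterwards to clear it, of 70.4% to 80.1%. The parental level enters both the change and the difference of the parents, so a share above 50% can arise with no effect, and among genes called in 1 of the 2 lines it was 71.1% of 1086 for RPK-1 and 61.1% of 1502 for RPK-9, with no value without an effect computed. A different route to resistance in each line is the biological explanation the design offers, and it was not tested.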

How the results depend on the processing

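Signal over background and the 2 arrays per line limit these results. The common floor and the substitution of the median spot signal in normexp were chosen after seeing the data. Normexp on the mean spot signal was not run as planned, the deposited value table equalled the scanner values, and slide as a block could change nothing, since each line pair lies on 1 slide. Quantile normalization, the variance trend, the mean of a gene's probes, both replicate blocks and the other DCK probe moved no total count of calls by over 1.5 times, although quantile normalization moved the lower calls in RPK-59 from 432 to 765, the shared higher genes from 17 to 9 and the opposite calls of RPK-9 and RPK-59 from 117 to 187. DCK kept its calls in RPK-1 and RPK-9, with log2 differences from -7.64 to -3.21 and from -6.48 to -2.39. In RPK-59 it was not called under any alternative run for DCK, with -0.523 to -0.237. Those values are under 2-fold and could not be called at any p, so they do not show that DCK was unchanged. In the reported setting its limma adjusted p of 0.174 would also fail without the fold minimum. The ranges for RPK-1 and RPK-9, here and without single arrays, include signals not well above background and follow the floor of each setting, so they are not measured changes. Over the alternatives the named genes gave 2465 values with the same direction and side of the threshold, 326 that lost a call, 17 that gained one and 12 that reversed.

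Normexp with quantile called 819 genes in RPK-1, 1282 in RPK-9, 537 in RPK-59, 9 shared by all lines and 228 for the mean, and MSMB in RPK-59 reversed to -0.014. Normexp with the 75th percentile called 592, 974 and 136 genes in the 3 lines, 0 shared and 192 for the mean, 1411, 437 and 953 for the differences of RPK-1 from RPK-9, RPK-1 from RPK-59 and RPK-9 from RPK-59, and 9 gene lists, and under it the median of all genes was -0.142 in RPK-1 and 0.103 in RPK-59, against 0.024 and 0.037 in the reported setting. It reversed CDH7 to -0.056, COL11A2 to -0.36, KLRG1 to -0.60, LKAAEAR1 to -0.12, PPP1R1C to -0.57, PRKAR2B to -0.61, RCAN2 to -0.72 and TLR5 to -0.64 in RPK-1, and BAG2 to 0.13, HEY1 to 0.28 and OR2A7 to 0.20 in RPK-59. For both, the cause was not tested. Of the 838 calls in RPK-59, 734 were kept in direction and call under quantile normalization, 457 under normexp with quantile and 135 under normexp with the 75th percentile, and 571 and 627 without replicates 1 and 2 of RPK-59.

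With no filter 20 genes were shared, and the median of all genes was 0.163 in RPK-59. Overlaps between 2 lines kept within 1.5 times in 105 values and moved further in 39, under both normexp settings, the filter on all arrays, the fold settings, quantile normalization and some left-out arrays. A filter on all 12 arrays, which tests fewer genes, called 1022, 1339 and 460 in the 3 lines, 17 shared and 222 for the mean. Without a fold minimum these counts were 3237, 4048, 1568, 89 and 3529, and with treat against 1.5-fold 786, 1288, 275, 2 and 372, with 1709, 688 and 1251 for the differences. Counted as probes they were 2808, 3776, 1452, 48 and 1487, with 5250, 2782 and 4407 for the differences. A common floor gave 579 genes for the mean, the 4 arrays of RPK-59 and PK-59 alone 15, and the line pair as the unit 0 by limma. With the line pair as the unit, 643 of 13877 genes had an unadjusted p under 0.05, no more than chance alone would give. An estimated correlation called 0 gene lists by camera, while fry called 6. Of the 63 camera tests with it, 2 had an unadjusted p under 0.05, no more than chance alone would give.

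The replicate block within line pairs called 1767 genes in RPK-1, 2175 in RPK-9, 1013 in RPK-59, 38 shared and 897 for the mean. The pairing ended the call of the interferon list in RPK-1 (camera adjusted p = 0.0816) and that of CDH7 in RPK-1, and it added calls for NT5E and SAMHD1 in RPK-9 and KRT6B in RPK-59, with no other change among the named genes. Leaving out each array in turn, with a lone array assumed to vary like the other lines, gave 1161 to 1489 genes in RPK-1, 1662 to 1948 in RPK-9, 591 to 1367 in RPK-59, 15 to 56 shared, 736 to 1115 for the mean, 2370 to 2864, 1131 to 1905 and 1884 to 2829 for the differences, and 2 to 7 gene lists. The fitted difference of DCK, not a measured change in RPK-1 and RPK-9, then ran from -7.64 to -7.31, from -6.48 to -6.08 and from -0.523 to -0.334 in the 3 lines.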

Other observations

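RRM1 stood in a stretch of chromosome 11 where 6 neighbouring tested genes rose in RPK-1, PGAP2 at 1.83 on the log2 scale, RHOG at 1.58, the calcium sensor gene STIM1 at 2.03, RRM1 at 1.35, the antibody receptor gene TRIM21 at 2.77 and TRIM68 at 1.46. Nearby TRIM5, TRIM6, TRIM34 and TRIM22 rose too, at 1.71, 1.54, 1.80 and 3.06. In RPK-9, RRM1 and TRIM21 were called, at 2.24 and 2.99, and TRIM5 at 1.06, whereas PGAP2 was at 0.62, STIM1 at 0.60 and TRIM68 at -0.74. On chromosome 15 the imprinted gene SNRPN was at least 54.8-fold lower in RPK-1 and at least 112-fold lower in RPK-9, and its neighbour IPW was at least 13.7-fold and 30.1-fold lower. In the PK-59 pair neither was well above background. On chromosome 19, RPK-9 had lost the signal of RFX1, at least 46.9-fold lower, IL27RA, at least 44.4-fold, SAMD1, at least 30.9-fold, and DCAF15, at least 12.2-fold, while RPK-1 had RFX1 at -0.03 and DCAF15 at 0.09.

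Runs of neighbouring genes called alike in RPK-9 held members of several gene families, named here after their values were seen and not tested as groups. The glutathione transferase genes GSTA1 and GSTA2 rose, at least 22.4-fold and by 2.45 on the log2 scale, as did the adhesion genes CEACAM6 and CEACAM7, at 5.18 and 5.33, and the alcohol dehydrogenase genes ADH1A and ADH1C, at least 65.0-fold and 139-fold. The metal-binding genes MT2A, MT1X and MT1E fell, at -1.82, -2.09 and -2.15, and HLA-G, which belongs to MHC class I, at -1.58. The natural killer receptor genes KLRC2 and KLRC4 fell in RPK-9, at -2.48 and -2.40, and rose in RPK-59, at 3.16 and 2.62. Probes of such families can share signal between near-identical members. Over all runs, 419 of 419 members kept their direction under quantile normalization and under normexp with quantile, and 402 under normexp with the 75th percentile, where those that turned lay in runs that were higher in RPK-1. Of the 419, 396, 266 and 216 were still called under these 3 settings.

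For the mean of the 3 changes, 2 of 100 relabellings within the line pairs, drawn from 108 possible ones, called as many genes as the real labels with its 882, the real one included. The highest other, 953, turned the direction of the PK-9 pair, turning PK-1 gave 817 and turning PK-59 gave 708, while the highest that mixed arrays within a pair gave 551. Mixed groups put the difference between the 2 lines of a pair into the spread. Their lower counts thus show only that arrays group by line within the pairs. The count of genes for the mean does not set the real direction apart from a turned one.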
